A study of Mus musculus and Homo sapiens with 10 samples.

How the data were processed

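The series comprised 10 native chromatin immunoprecipitation libraries, made from chromatin cut with micrococcal nuclease. Per the labels, 6 came from 46c mouse embryonic stem cells (mESC), a line with a Sox1-GFP reporter, at passages 25 to 28, with 2 replicates each for H3K122ac, H3K64ac and H3K27ac. The other 4 came from K562, a human erythroleukaemia line, at passage 14, with 1 library each for H3K122ac, H3K27ac, H3K4me1 and input chromatin. Samples were grouped by cell line and antibody from their titles.

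Per the submitters' processing notes, the tools were Bowtie 0.12.8, HOMER 4.3 and SICER 1.1, and the builds mm9 for mouse and hg19 for human. The roles of the tools are not given in the sources used here. The column order and arithmetic of the deposited lists are those of the SICER caller, which joins enriched windows into islands. Per the labels of the lists, the window was 200 bp, the false discovery rate 0.01, and the gap allowed inside an island 200 bp for H3K27ac and 600 bp for the other marks. The smallest gaps between islands, 400 bp for H3K27ac and 800 bp for the others, were checked against these settings. The 2 mouse replicates of each mark were merged by the authors before islands were called, so 6 lists were analysed, 3 per cell line, and no list of a single replicate was used here.

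Each deposited list gives, for every island, whole-number read counts of the immunoprecipitated library and of a background library, not normalized by the authors. It also gives a p-value against background and a q-value adjusted for multiple tests, both from the authors' caller. The deposited fold is the ratio of the 2 counts divided by a single library ratio per list. That ratio was recomputed from the counts and was constant within each list, with a background count of 0 entered as 0.25. It was 0.913 for mESC H3K122ac, 1.08 for mESC H3K64ac, 2.19 for mESC H3K27ac, 0.258 for K562 H3K122ac, 0.688 for K562 H3K27ac and 0.581 for K562 H3K4me1. Islands with identical ends in a pair of lists of the same cell line always had the same background count, so the lists of a cell line shared a background library. Which library served as background is not given in the sources used here for the lists of either cell line. Folds are the authors' and were compared only within a list.

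The overlap of a pair of lists was the share of islands of the first list that met an island of the other by at least 1 bp. It was set against a 2-sided circular-shift permutation test, in which the second list was moved along each chromosome 1000 times. This keeps island lengths and clustering, but not the positions shared through a common background library. The smallest p-value that 1000 shifts can give is 0.000999, and 0.00498 for the 200 shifts used for alternatives. The same shifts gave the chance value of the log2 difference in median fold between islands with and without H3K27ac, and of the log2 odds ratio of meeting H3K4me1, with 0.5 added to each cell. In total 16 main tests were adjusted by the Benjamini-Hochberg method, and 9 of them were fixed in advance; each adjusted p-value was 0.000999. With 1 list per mark there was no replicate test, and every p-value describes these lists rather than the spread between cultures. Shares carry Wilson 95% intervals, which cover counting error only, as neighbouring islands are not independent. Islands were divided into deciles of fold after islands with fewer than 10 background reads were set aside.

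The 9 tests named as fixed in advance, the first set of alternatives and the rule for named regions were fixed before the data were examined. The rule took, in each of 7 classes of islands, the 2 islands of highest fold and the 2 longest on numbered chromosomes and X. They needed at least 100 reads and at least 10 background reads, and, for a class lacking a mark, no island of that mark within 5000 bp. It also took the 2 chromosomes with the highest and the 2 with the lowest share of H3K122ac islands without H3K27ac. Regions are given as 1-based coordinates of mm9 or hg19. Gene lists fixed in advance were not scored and regions were not assigned to genes, because no annotation of these builds was used here. The gene table at hand was for another mouse build.

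Alternatives were an overlap of at least 50% of the island, a distance of 1000 bp, a q-value of at most 1e-10, a fold of 3 or more in either list, and the 20000 islands of highest fold per list. Further ones were H3K27ac islands joined across 600 bp, numbered chromosomes only, local shifts of 100 kb to 1 Mb, and shares of base pairs. A ranking by excess read density, and a split of each first list at its median background reads per kb, were added after seeing the data. Excess read density is the ChIP count divided by the library ratio, minus the background count, per kb of island. For K562, background reads per kb of island were also summed over the 3 lists in bins of 1 Mb that held at least 20000 bp of islands.

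The code was tested on simulated data with the island lengths of the mESC H3K122ac and H3K27ac lists. Planted overlaps were recovered to within 0.218 percentage points in lists of about 19530 islands, and 0 of 900 islands differed from a direct search. For 100 pairs of unrelated lists, 3 gave an overlap p-value and 0 a fold-difference p-value under 0.05. Simulated islands were placed at random, without clustering or a shared background library. These rates therefore do not cover either feature of the deposited lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.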

Results

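Acetylation of 2 lysines in the globular domain of histone H3, K122 and K64, was mapped beside the tail mark H3K27ac, which is commonly used to mark active promoters and enhancers. In K562 cells H3K4me1, a mark typical of enhancers, was mapped as well. The study asks whether globular-domain acetylation marks regulatory regions, among them regions without H3K27ac. In mESC, the merged H3K122ac list held 92957 islands over 236.2 Mb, with 44320255 reads inside them and a median length of 1800 bp. The H3K64ac list held 57512 islands over 210.0 Mb, with 38692934 reads and a median length of 2600 bp. The H3K27ac list held 122097 islands over 195.2 Mb, with 40473895 reads and a median length of 1200 bp. In K562, H3K122ac gave 72662 islands over 191.0 Mb with 18283729 reads, H3K27ac 173981 islands over 314.9 Mb with 34195325 reads, and H3K4me1 113669 islands over 365.1 Mb with 35562145 reads. Median folds over background were 2.83, 2.42 and 1.49 for H3K122ac, H3K64ac and H3K27ac in mESC, and 5.34, 2.27 and 2.72 for H3K122ac, H3K27ac and H3K4me1 in K562. There were no replicate lists.

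The first comparison asked how far H3K122ac and H3K27ac occupy the same regions in mESC. Of the H3K122ac islands, 55.6% (Wilson 95% interval 55.3 to 55.9%) met an H3K27ac island, and 41297 did not. Shifted H3K27ac lists met 17.1% of them on average, with a range of 16.3 to 18.9%, so the observed share was 3.25 times the chance value (p = 0.000999, circular-shift permutation test, the smallest it can give). It was 2.64 times the 21.1% met by local shifts of 100 kb to 1 Mb, 5.80 times chance with 50% of the island covered and 12.7 times for the 20000 islands per list of highest fold. H3K122ac islands with H3K27ac were longer, with a median of 2400 bp against 1400 bp, and had a higher median fold over background, 3.31 against 2.34. Background itself was lower in them, at a median of 58.3 reads per kb against 67.8. Shifted lists met 29.2% of H3K122ac islands over 4000 bp and 11.1% of those up to 1000 bp. Part of the length difference is thus expected by chance, as it is for mESC H3K64ac and K562 H3K122ac below. Among H3K122ac islands without H3K27ac, 14004 still reached a fold of 3 or more. The log2 difference in median fold was 0.50, against 0.06 for shifted lists (permutation p = 0.000999), and islands with H3K27ac had the higher median on 20 of 20 chromosomes. The islands without H3K27ac lay a median of 8400 bp from the nearest H3K27ac island, and 2907 of them lay over 50000 bp away.

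Among H3K122ac islands with no H3K27ac island within 5000 bp, the highest folds belonged to chr3:6849401-6850200 (mm9), at 32.2 from 323 reads over 11 background reads, and chr4:26644801-26646000, at 30.4 from 416 reads over 15. Both met an H3K64ac island, with H3K64ac folds of 11.1 and 11.2. The longest such islands were chr1:74813601-74831400, of 17800 bp with a fold of 2.51, and chr6:88143201-88160600, of 17400 bp with a fold of 2.30. Each of these also met H3K64ac. Where all 3 acetylations were present, the highest H3K122ac folds were 33.3 at chr12:115344201-115344800, over 10 background reads, and 32.7 at chr9:10946201-10948400, over 13. At the latter, H3K64ac reached a fold of 31.4 and H3K27ac 14.8. Low counts in the shared background library may have raised these folds together. The longest island with all 3 marks, chr4:130172601-130220800, spanned 48200 bp and held 18 separate H3K27ac islands, followed by chr10:80388201-80432600 with 44400 bp and 8 H3K27ac islands. The share with H3K27ac fell to 36.7% at a q-value of at most 1e-10, to 34.5% and 30.6% for the 20000 islands per list of highest fold and of highest excess read density, and to 3.69% when H3K27ac islands needed a fold of 3 or more, which 4.44% of them reached. The log2 fold difference fell to 0.11 among H3K122ac islands with a fold of 3 or more, 0.17 for the 20000 of highest fold and 0.32 with 50% of the island covered, and rose to 1.40 with a fold of 3 or more in H3K27ac.

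**Figure D1:**
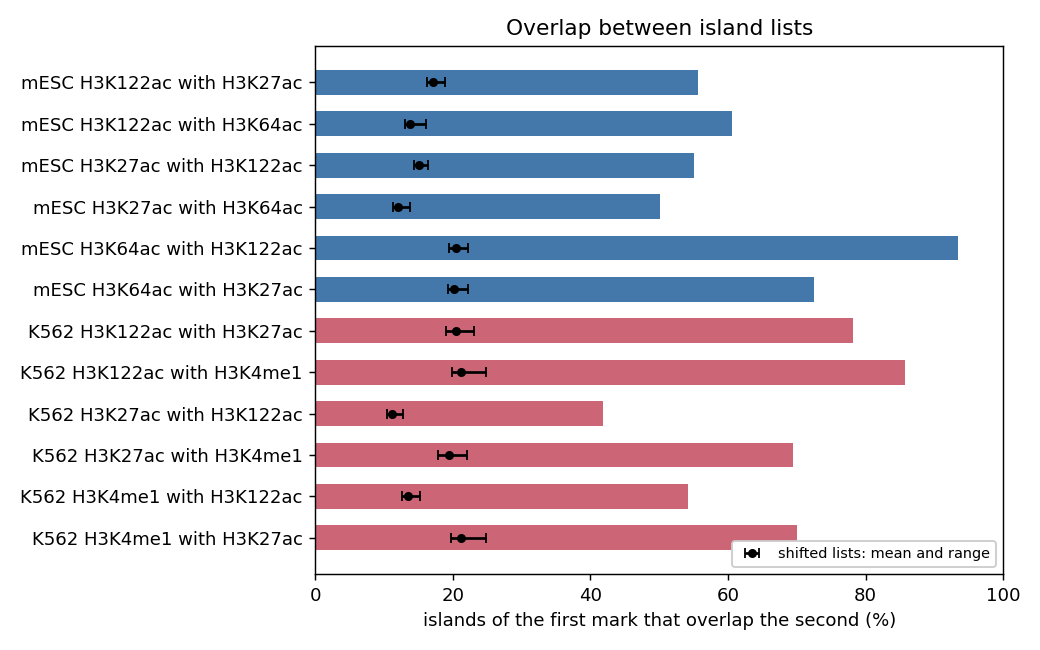
Share of islands of a first mark that met an island of a second mark by at least 1 bp, in percent, for the 12 ordered pairs of lists (blue, mESC; red, K562). Black points and bars give the mean and range of 1000 shifted lists, and every observed share lies above its range, from 41.9% for K562 H3K27ac with H3K122ac to 93.5% for mESC H3K64ac with H3K122ac.

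H3K64ac was set against both other acetylations in mESC. Nearly every H3K64ac island carried H3K122ac: 93.5% (93.3 to 93.7%) met an H3K122ac island, against 20.5% for shifted lists (range 19.4 to 22.2%; p = 0.000999, circular-shift permutation test). H3K27ac was met by 72.5% (72.2 to 72.9%) of H3K64ac islands, against 20.2% for shifted lists (permutation p = 0.000999), which left 15803 without it. Of these, 14210 carried H3K122ac and 1593 carried neither other mark. In the opposite direction 60.6% of H3K122ac islands met H3K64ac, 4.41 times the mean of shifted lists. H3K64ac islands with H3K27ac had a median fold of 2.72 and a median length of 3000 bp, against 1.81 and 2000 bp without it, a log2 difference in fold of 0.59 (shifted lists 0.05; permutation p = 0.000999) that was positive on 20 of 20 chromosomes. Their background was lower as well, at 56.0 reads per kb against 65.5.

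The H3K64ac islands of highest fold with no H3K27ac island within 5000 bp were both on chromosome X, chrX:116733601-116736600 with a fold of 39.3 and chrX:118057201-118059400 with a fold of 37.0. Their H3K122ac folds were 29.9 and 35.3. These islands held 16 and 11 background reads over 3000 and 2200 bp, so low counts in the shared background may have raised both folds. Background reads per kb of H3K64ac islands were lower on X than on the numbered chromosomes, at 27.8 against 58.9. The longest were chr5:150170201-150186400 at 16200 bp and chr4:137271801-137287200 at 15400 bp, with low folds of 1.56 and 1.41. The fold difference was lost among H3K64ac islands with a fold of 3 or more, at -0.05 on the log2 scale against -0.03 for shifted lists (permutation p = 0.144); it was 0.34 with 50% of the island covered and 1.53 with a fold of 3 or more in H3K27ac. Overlaps with H3K27ac and H3K122ac fell to 41.7% and 62.4% for the 20000 islands per list of highest fold, to 40.7% and 60.6% by excess read density, and to 5.47% and 57.9% with a fold of 3 or more in the second list.

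The 3 mESC marks divided the H3K122ac islands into 4 classes. Median folds, which were not tested between classes, were higher in the classes with H3K64ac. The largest class, 41369 islands or 44.5% (44.2 to 44.8%), carried H3K27ac and H3K64ac and had a median fold of 3.69 and a median length of 2800 bp. A further 14946 islands (16.1%) carried H3K64ac without H3K27ac, with a median fold of 2.87. The 10291 islands with H3K27ac alone had a median fold of 2.21, and the 26351 (28.3%) with neither mark 2.10 and a median length of 1000 bp. H3K64ac was met by 80.1% of H3K122ac islands with H3K27ac and by 36.2% (35.7 to 36.7%) of those without. Shifted H3K64ac lists met 14.9% and 12.3%, and each share exceeded every shift (p = 0.000999, circular-shift permutation test). The log2 odds ratio was 2.83, against 0.32 for shifted lists.

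H3K27ac without globular-domain acetylation was also frequent in mESC. Of the 122097 H3K27ac islands, 48933 (40.1%; 39.8 to 40.4%) met neither H3K122ac nor H3K64ac, and 55267 met both. Median H3K27ac folds were 1.44 and 1.58 in these classes, and median lengths 1000 and 1400 bp. By length, the islands with neither mark covered 58.3 of the 195.2 Mb. The H3K27ac library was the deepest against background, with a library ratio of 2.19 against 0.913 for H3K122ac and 1.08 for H3K64ac. Weak H3K122ac or H3K64ac may therefore have gone uncalled. With neither mark within 5000 bp, the highest H3K27ac folds were 12.1 at chr10:20552801-20553600, over 13 background reads, and 10.3 at chr16:89676201-89677000, over 10. The longest such islands, chr17:57034401-57052000 of 17600 bp and chr15:72942401-72959600 of 17200 bp, had folds of 1.15 and 1.1, close to the lowest called in the list, 1.05.

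**Figure D2:**
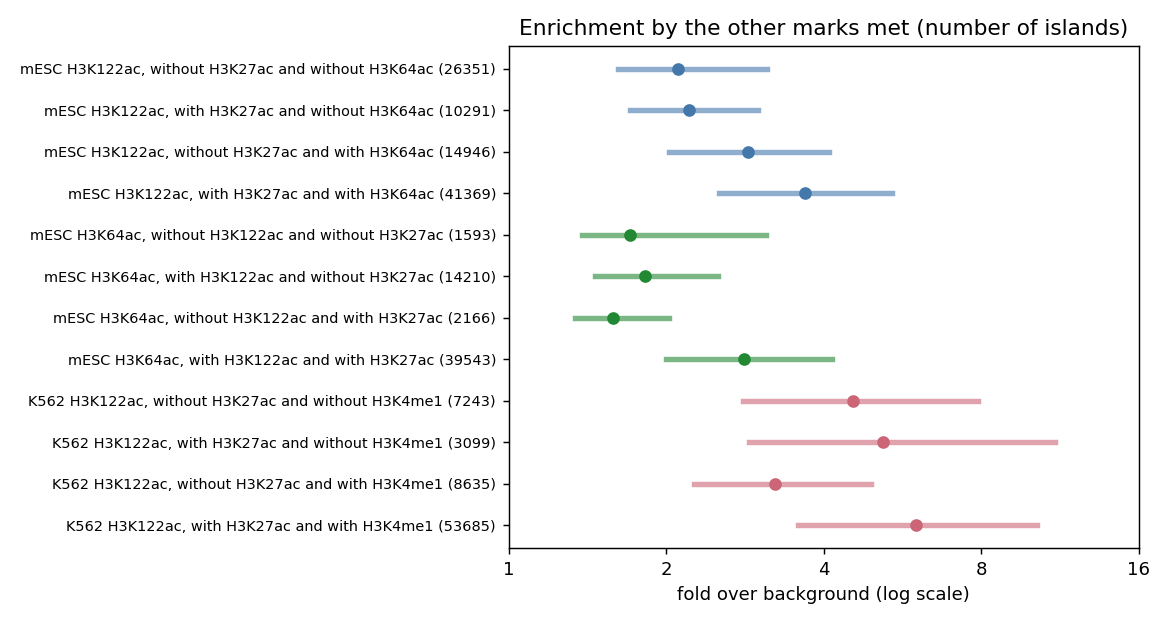
Fold over background of H3K122ac and H3K64ac islands, on a log axis, by the other marks each island met (blue, mESC H3K122ac; green, mESC H3K64ac; red, K562 H3K122ac). Points are medians, bars the interquartile range, and numbers in brackets the islands; folds are comparable within a list only, and islands with both other marks had the highest median of each list, 3.69, 2.81 and 6.0.

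In K562 the same question was put to H3K122ac and H3K27ac. H3K27ac was met by 78.1% (77.8 to 78.4%) of H3K122ac islands, against 20.4% for shifted lists (range 19 to 23.1%), 3.83 times the chance value (p = 0.000999, circular-shift permutation test), and 2.57 times the 30.4% met by local shifts. The 15878 islands without H3K27ac were shorter, with a median of 1200 bp against 2200 bp, and had a lower median fold, 3.67 against 5.96, at the same median background of 52.5 reads per kb. The log2 difference was 0.70, against 0.06 for shifted lists (permutation p = 0.000999), and it was positive on 23 of 23 chromosomes, from 0.44 to 1.05. Islands without H3K27ac lay a median of 12400 bp from the nearest H3K27ac island, and 3164 of them lay over 50000 bp away. When H3K27ac islands needed a fold of 3 or more, the overlap fell to 40.9%, against 7.53% for shifted lists, and the log2 fold difference rose to 1.34. That difference fell to 0.46 among H3K122ac islands with a fold of 3 or more, and to 0.41 and 0.43 for the 20000 islands per list of highest fold and of highest excess read density. Whether the overlap differs between the cell lines was not tested, since organism, depth and replicate merging differ as well.

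H3K27ac extended beyond H3K122ac in K562. Of 173981 H3K27ac islands, 101117 (58.1%) met no H3K122ac island, and 52446 of these met H3K4me1. The share of H3K27ac islands with H3K122ac rose from 28.7% in the lowest decile of H3K27ac fold to 89.8% in the highest. With no H3K122ac island within 5000 bp, the highest H3K27ac folds were 11.1 at chrX:123122401-123123000 (hg19) and 10.1 at chr1:93576801-93577800, where H3K4me1 folds were 9.15 and 4.60. The longest were chr9:134060001-134091200 at 31200 bp and chr22:23605001-23632800 at 27800 bp, with folds of 1.44 and 1.11. Their background counts were high, at 6042 and 6840 reads. The K562 H3K122ac library was the shallowest, with a library ratio to background of 0.258 against 0.688 for H3K27ac.

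H3K4me1 was used to ask whether K562 H3K122ac islands without H3K27ac lie in enhancer-like chromatin. H3K4me1 was met by 85.8% (85.5 to 86.0%) of all H3K122ac islands, against 21.2% for shifted lists (range 19.8 to 24.9%; p = 0.000999, circular-shift permutation test). Among H3K122ac islands with H3K27ac the share was 94.5% (94.4 to 94.7%). Among those without H3K27ac it was 54.4% (53.6 to 55.2%), which was lower but still 3.04 times the mean of shifted lists, 17.9%, and above the highest shift, 19.9%. The log2 odds ratio between these groups was 3.86, against 0.38 for shifted lists (permutation p = 0.000999). The class with H3K4me1 and without H3K27ac held 8635 islands, 11.9% (11.7 to 12.1%) of the list, with a median fold of 3.23 and a median length of 1200 bp. The 53685 islands with both marks had a median fold of 6.0 and a median length of 2400 bp, and the 7243 with neither mark a median fold of 4.54. Background was lower in the islands with neither mark, at 45 reads per kb, than in the 8635 islands, at 58.1.

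Among H3K122ac islands with H3K4me1 and no H3K27ac island within 5000 bp, 871 had enough reads to be named. The highest folds were 34.3 at chr14:74078801-74080200, from 133 reads over 15 background reads, and 28.8 at chr12:121077801-121078400, from 104 reads over 14, where H3K4me1 folds were 3.38 and 2.21. The longest, chr21:44864001-44873200 and chr22:19597801-19607000, each spanned 9200 bp, with folds of 3.04 and 1.48. With all 3 K562 marks, the highest H3K122ac folds were 60.8 at chr2:240323001-240324400, over 27 background reads, and 60.6 at chr17:9548001-9549600, over 17. The longest were chr3:45078201-45156600, of 78400 bp with a fold of 6.76, and chr1:31195001-31263000, of 68000 bp with a fold of 7.53. The overlap of H3K122ac with H3K4me1 fell to 50.8% when H3K4me1 islands needed a fold of 3 or more. For the 20000 islands per list of highest fold and of highest excess read density it fell to 44.7% and 44.6%, and the log2 odds ratio to 2.41 and 1.74.

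Overlap with H3K27ac rose with the enrichment of the globular-domain marks. For mESC H3K122ac it rose from 33.8% (32.9 to 34.8%) in the lowest decile of fold to 76.2% (75.3 to 77.0%) in the highest. For K562 H3K122ac it rose from 59.8% (58.7 to 61.0%) to 94.9% (94.4 to 95.4%). For mESC H3K64ac it rose from 46.7% to 89.6% in decile 9 and was 85.7% (84.8 to 86.6%) in decile 10. Median length differed too, for mESC H3K122ac from 1600 bp in decile 1 to 2400 bp in decile 9. The rise with fold was not split by length or set against shifted lists, so length may account for part of it. The excess over shifted lists was present at every length: in each of 4 length ranges of each list, from 200 bp upward, the share with H3K27ac was 2.86 to 4.75 times that of shifted lists (p = 0.00498 in each, circular-shift permutation test). Because the lists of a cell line share a background library, which shifts do not keep in place, part of an excess may come from that library. The rise with fold, and the fold differences between islands with and without H3K27ac, were not split by background density. Part of them may come from that library as well. Among islands of the first list at or above their median background reads per kb, the 5 overlaps fixed in advance were 2.61 to 4.44 times those of shifted lists, and among islands below it 3.86 to 4.70 times. In mESC, H3K27ac was met by 46.1% of H3K122ac islands at or above the median background and by 65% below it, and by 65.2% and 79.8% of H3K64ac islands. In K562 the shares of H3K122ac islands were 78.2% and 78.1%.

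**Figure D3:**
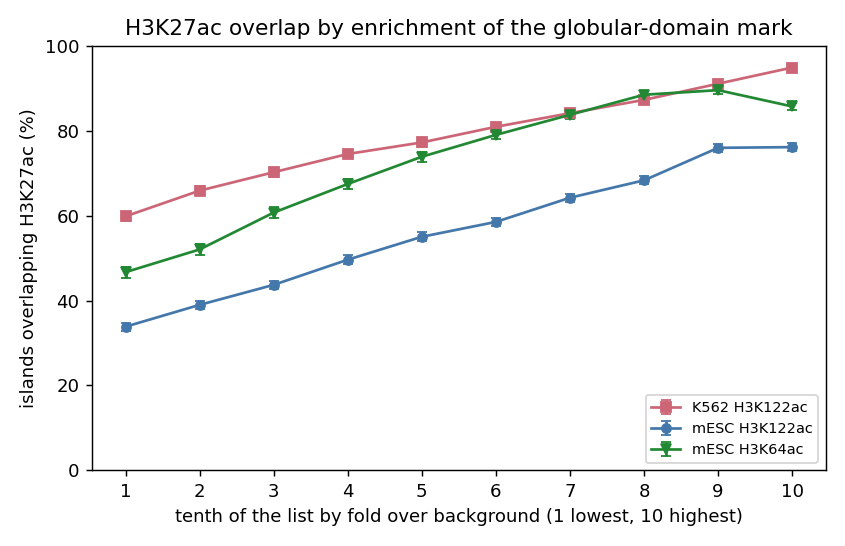
Share of islands meeting H3K27ac, in percent, by decile of fold over background within each list (1 lowest, 10 highest), with Wilson 95% intervals, for K562 H3K122ac, mESC H3K122ac and mESC H3K64ac. In the highest decile the shares were 94.9%, 76.2% and 85.7%.

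The share of H3K122ac islands without H3K27ac varied by chromosome. In mESC it was highest on X, at 53.8% (51.8 to 55.7%) of 2508 islands, and on chromosome 4, at 49.0% (47.8 to 50.3%). It was lowest on chromosome 18, at 38.0% (36.3 to 39.7%), and on chromosome 16, at 38.3% (36.7 to 40.0%). In K562 it was highest on chromosome 18, at 28.3% (26.1 to 30.7%), and on chromosome 13, at 27.7% (25.5 to 30.0%), and lowest on chromosome 15, at 18.1% (16.6 to 19.7%), and on chromosome 14, at 19% (17.4 to 20.7%). Neighbouring islands are not independent, so these intervals cover counting error only. On mESC X, background was 29.8 reads per kb of H3K122ac island and 1672 H3K27ac islands were called. On chromosome 4 the values were 63.9 and 6918, so lower depth may affect the share on X.

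**Figure D4:**
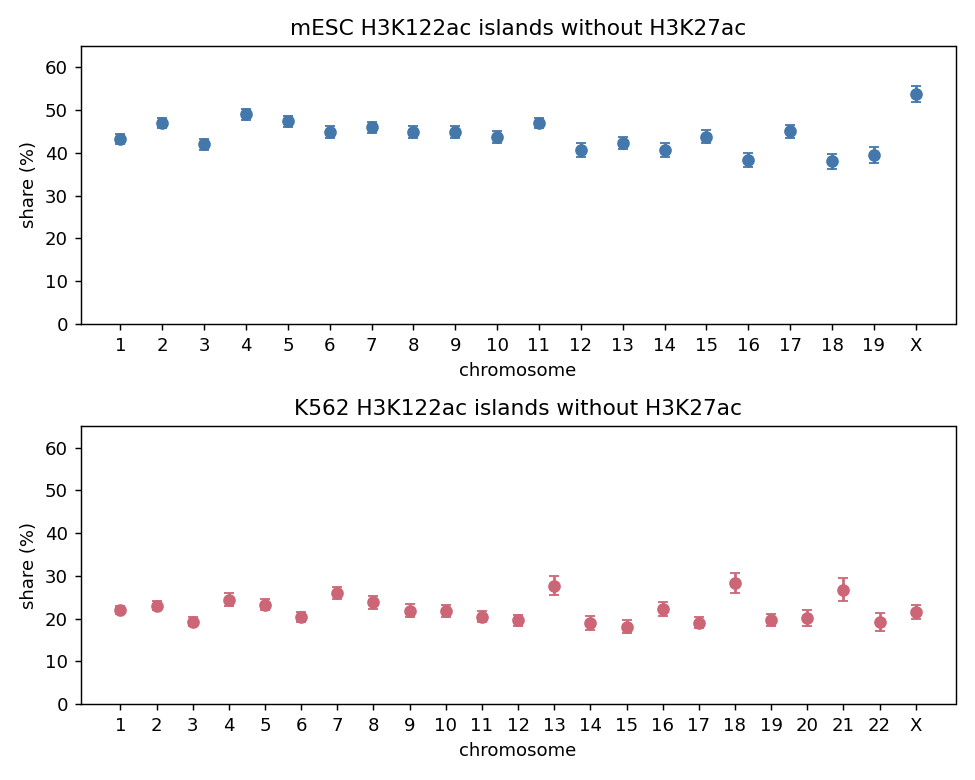
Share of H3K122ac islands without H3K27ac on each chromosome, in percent, with Wilson 95% intervals, for mESC (upper panel) and K562 (lower panel). The mESC shares run from 38.0% on chromosome 18 to 53.8% on X, and the K562 shares from 18.1% on chromosome 15 to 28.3% on chromosome 18.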

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

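The 12 results fixed in advance were recomputed under the alternatives, which gave 118 values. Local shifts and shares of base pairs were run for the 5 overlaps alone. The split by background density is not among the 118 values. The ranking by excess read density was chosen after seeing the data. In 107 of the 118 the direction and the side of the threshold were kept, or a count stayed within 1.5 times its main value. Every overlap stayed above its shifted lists (p = 0.00498 in each, circular-shift permutation test, the smallest 200 shifts can give). The multiple of chance, 3.25 to 4.56 for the 5 overlaps, was 2.57 to 3.43 against local shifts, 5.48 to 7.93 for base pairs, 5.80 to 10.3 with 50% of the island covered and 4.68 to 6.34 with a fold of 3 or more in the second list. For the 20000 islands per list it was 8.08 to 14.2 by highest fold and 7.42 to 12.9 by excess read density. The exceptions were 10 counts and 1 fold difference. Joining H3K27ac islands across 600 bp changed no value, so that setting says nothing about stability. The mESC H3K122ac islands without H3K27ac, 41297 in the main count, numbered 14004 with a fold of 3 or more in the first list, 89525 with that fold in H3K27ac, 13100 among the 20000 islands of highest fold and 13877 among the 20000 of highest excess read density. The mESC H3K64ac islands without H3K27ac, 15803 in the main count, numbered 28558 when 50% of the island had to be covered, and 2793 and 54365 with a fold of 3 or more in the first list and in H3K27ac. The K562 H3K122ac islands with H3K4me1 and without H3K27ac, 8635 in the main count, numbered 4787, 1935 and 2272 with a fold of 3 or more in the first list, by highest fold and by excess read density. Except for the 50% rule, which makes an overlap harder to meet, these settings shorten a list by construction. The fold difference of mESC H3K64ac turned to -0.0499 (permutation p = 0.144) with a fold of 3 or more in the first list; the cause was not tested, though the filter removes the low folds being compared. No paired analysis was possible because the mouse replicates were merged before islands were called, and for the same reason leaving out each replicate was not run. Depth limits what lack of H3K27ac means. Background counts like those of the mESC H3K122ac islands without it were taken as the measure. Over these, called H3K27ac folds had a minimum of 1.18, a 5th percentile of 1.21 and a median of 1.40. In K562 the values were 1.35, 1.45 and 2.08. Weaker H3K27ac than the minimum was not called. The minimum is not a detection limit, so some H3K27ac above it may have been missed too.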

Other observations

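K562 H3K4me1 islands fell into 4 classes by acetylation. Both acetylations were met by 52849 islands (46.5%; Wilson 95% interval 46.2 to 46.8%), which had a median length of 3000 bp and a median H3K4me1 fold of 3.44. H3K27ac without H3K122ac was met by 26740 islands (23.5%), with a median fold of 2.37, and H3K122ac without H3K27ac by 8801 (7.74%), with a median fold of 2.17. The 25279 islands with neither acetylation (22.2%) had a median length of 1200 bp and a median fold of 2.12. In the lowest decile of H3K4me1 fold 46.6% of islands met H3K27ac and 28.4% met H3K122ac. In the highest decile 90.9% and 80.1% did.

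The rankings by excess read density, the split by background density and the test on the K562 segment of high background were chosen after the overlaps had been seen, while the other tests had their outcomes set before. For the mESC H3K122ac islands without H3K27ac, weak islands near the calling threshold would leave few of them in the top decile of fold, but 23.8% of that decile lacked H3K27ac, and 22.5% did so on numbered chromosomes alone. Background was lower in the top decile of fold, at 22.5 reads per kb for islands without H3K27ac against 42.2 with it. Low background may have raised some of these folds. In the top decile of excess read density 18.7% lacked H3K27ac, at 66.5 background reads per kb against 58.9 with it. Low background does not account for those islands. That ranking picks islands of higher background, however, so it cannot decide the cause in the top decile of fold. Over the whole set without H3K27ac, background reads per kb were 1.16 times those of islands with H3K27ac. H3K64ac was met 2.94 times as often as in shifted lists, and 2.71 times among islands at or above the median background density, which argues against chance calls of a single antibody and dips of the shared background library as the whole cause, though 26351 islands met neither other mark. Weak islands stay open for those with a fold under 3, and a low yield of the H3K27ac immunoprecipitation, whose median fold was 1.49 and of whose islands 4.44% reached a fold of 3, stays open for weak and strong ones alike. H3K27ac missed over high background stays open too, since 46.1% of H3K122ac islands at or above the median background density met H3K27ac against 65% below it; no biological explanation was tested.

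The K562 H3K122ac islands without H3K27ac gave a different picture. Low background counts over the whole set were argued against by a ratio of background reads per kb of 1. The classes differed, however, with 45 reads per kb for the 7243 islands with neither other mark and 58.1 for those with H3K4me1. Islands with H3K27ac and no H3K4me1 also had 45, and those with both marks 52.9. Low background therefore stays open for the islands with neither mark. The high-fold members depended on the ranking. By fold, 5.09% of the top decile lacked H3K27ac, which left weak islands near the calling threshold undecided, while by excess read density 0.564% did, 41 of 7267 islands. The ranking by excess read density picks islands of higher background, so this drop cannot decide whether low background raised the folds. In the top decile of fold, background was 16.7 reads per kb without H3K27ac and 35.6 with it. Folds raised by low background therefore stay open for these islands. H3K4me1 was met 3.04 times as often as in shifted lists, so part of the set lay in H3K4me1-marked chromatin. Islands with H3K27ac met it 4.27 times as often, so this overlap cannot explain the lack of H3K27ac. Local shifts were not run for these groups.

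Chromosomal segments of unusual background depth also stood apart. In mESC, H3K27ac islands per Mb on X were 0.207 times those on numbered chromosomes, against 0.414 for H3K122ac, and X had 28.8 background reads per kb of H3K122ac island against 62.5. Among islands with a fold of 3 or more the X ratios were 1.55 for H3K27ac and 0.827 for H3K122ac. The first was 1.88 times the second, which met the bound set beforehand for low read depth on X. This filter depends on depth itself, however, since the median H3K27ac fold was 2.41 on X against 1.49 on numbered chromosomes. Low read depth on X was therefore left undecided although its bound was met. In K562, 3 of 2272 bins had at least 3 times the median background density, all in chr22:21000001-24000000 (hg19), where H3K27ac islands had a median fold of 1.67 against 2.27 elsewhere and a median length of 3000 bp against 1200 bp. Background density in these bins was 3.17 to 4.31 times the median. H3K27ac reads per kb of island were 1.98 times those elsewhere, between the 1.2 set against extra DNA copies and the 2 set for them. Reads per kb of called islands also depend on which islands were called, so this test cannot decide, and extra copies stay undecided. The ratios were 1.45 for H3K122ac and 1.55 for H3K4me1, with no bound set. No biological explanation was tested for X or this segment.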
